A study of Mus musculus with 12 samples.

How the data were processed

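ChIP-seq libraries of LSD1, p65 and input chromatin were made from mouse bone marrow-derived macrophages, either untreated or treated with LPS (labelled 1 mg/ml) for 1 h, with 2 libraries in each of 6 groups. Groups were taken from the sample titles and antibody and treatment labels. The processed values used here were 1 annotated list of p65 regions after LPS intersected with LSD1 after LPS. Values of single libraries, of untreated cells and of input were not analysed here.

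Reads were mapped with Bowtie and analysed with HOMER on the mm9 build, per the submitters' processing notes, which give no versions. Per the file headers, the regions were annotated and their tags counted with HOMER's annotatePeaks program from 1 p65 and 1 LSD1 tag directory after LPS. Peak calling settings, the use of input, the pooling of the 2 libraries of a group and the distance that counted as an intersection are not stated in the sources used here. The list is labelled intersect500, which may be a distance in bp, but its unit and meaning are not explained. An LSD1 region may therefore lie beside a p65 region and not within it. The deposited signal of each region is a HOMER tag count scaled by the authors to an effective total of 10000000 tags, per the file headers, from 963063 p65 and 1297342 LSD1 tags. The deposited peak score was 0 in all 3959 entries and was not used; where a score had been planned for ranking or filtering, p65 tags took its place. The annotation class, the nearest TSS and its gene are those the authors' annotation gives.

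One tag was worth 10.4 units of p65 signal and 7.71 units of LSD1 signal. Division by these steps gave whole tags for every value within a tolerance of 0.01 tags (largest deviation 0.000633), and whole tags are reported throughout. The regions took 25767 p65 tags (2.68% of all) and 21128 LSD1 tags (1.63%). The list selects regions by p65, so their p65 tag numbers are biased upwards by selection. Poisson intervals of tag numbers and exact Clopper-Pearson intervals of shares, at 95%, cover counting error only. Reads carry no molecular identifiers, and with 1 value per antibody and region no replicate spread could be computed.

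Of the 3959 entries, 114 repeated a position already listed and were counted once, leaving 3845 distinct regions. Identifiers of 2154 entries had been turned into dates by a spreadsheet, so regions were identified by position. Coordinates are 1-based on mm9 as deposited. Genes were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, used for names and gene types only. Of the 3538 assigned genes, 3535 matched. The background of the list tests was the 21900 protein-coding genes of that table. Of 1805 regions inside an exon, intron or UTR whose transcript matched a gene, 146 (8.09%) had another gene as nearest TSS.

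The 15 gene lists (352 genes, all matched; Cxcl11, Mx1 and Mx2 were not protein-coding in the reference and were left out of the tests), the tests and the rule for named genes were fixed before the data were examined. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 15 lists and a threshold of 0.05. Among genes with a region, the share with one within 1000 bp of the TSS was compared likewise over 11 lists. Tags and regions per gene were compared by two-sided permutation tests with 100000 resamples, and rank correlations with 10000. The named genes were the 10 genes of the regions with most p65 tags, and the 5 genes with most regions. From each of 5 inflammatory lists and the interferon list came the 3 genes with a region closest to the TSS and the first 2 in alphabetical order without a region. Il6, Il1b, Tnf, Nfkbia, Ccl2, Rela, Kdm1a and Prkca were named whatever their values. Other members with a region were named after their values were seen.

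Alternatives used TSS windows of 500 and 2500 bp, the promoter class, merging of regions closer than 500 bp, gene assignment within 10000 or 1000 bp, all reference genes as background, regions above the median in p65 tags, regions with at least 5 LSD1 tags, regions outside repeats (the annotation names repeats in introns and between genes only, so other classes are all kept), every entry counted, autosomes, the gene of the overlapping transcript, and the LSD1 complex list without Prkca. On simulated data of 21900 genes for the list comparison, a list of 35 genes with a region in 50% of its members, against 15% of other genes, was called in 97% of 200 draws, and 0.464% of the other lists were called. No list with a deficit was simulated. Unchanged permutation tests gave a p under 0.05 in 5% of draws. The planned search for κB motifs, which needs sequence of mm9, and the planned test of LPS against untreated cells, which needs values per library, were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.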

Results

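Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map LSD1 and p65 on the genome of wild-type C57BL/6 mouse bone marrow-derived macrophages. LSD1, encoded by Kdm1a, is a histone lysine demethylase. p65, encoded by Rela, is the transactivating subunit of NF-κB. Lipopolysaccharide (LPS) is the bacterial cell wall component that activates NF-κB through Toll-like receptor 4. The series holds 12 libraries in 6 groups of 2, namely input, LSD1 and p65 libraries from untreated cells and from cells given LPS for 1 h. Untreated and LPS-treated cells alike were labelled with 24 h of serum starvation. The values used here are the authors' list of p65 regions after LPS that were intersected with LSD1 regions after LPS, called shared regions below, each with a p65 and an LSD1 tag number (a tag is a mapped read). The p65 values came from 963063 tags and the LSD1 values from 1297342 tags. The list gives 1 value per antibody and region, so no value has a replicate SD, and all intervals cover counting error only.

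The first question was where in the genome p65 and LSD1 were found together 1 h after LPS. The list held 3845 distinct regions of 236 bp, covering 907.42 kb. Shared regions lay mainly at gene starts: 2834 of them (73.7%, exact 95% binomial interval 72.3 to 75.1%) had their centre within 1000 bp of a transcription start site (TSS). Most of these sat just inside the gene, with 2076 downstream and 756 upstream of the TSS (73.3% downstream, interval 71.6 to 74.9%; two-sided exact binomial test, p = 6.47e-141). The fullest 100 bp step was the first one downstream, with 520 regions, against 350 in the first step upstream, and the median distance over all regions was 146 bp downstream.

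By the annotation of the list, 1436 regions (37.3%, interval 35.8 to 38.9%) were in the promoter class, 814 (21.2%) in introns, 652 (17.0%) in exons, 340 (8.84%) in 5' UTRs and 506 (13.2%) between genes. Transcription termination sites held 56 regions, non-coding transcripts 31 and 3' UTRs 10. CpG islands were common in introns and between genes, covering 840 of the 1320 regions of these classes, many of them near a TSS (63.6%, interval 61.0 to 66.2%). Of the 758 such regions beyond 1000 bp from a TSS, 309 (40.8%, interval 37.2 to 44.4%) were also in a CpG island. Distal regions were the minority, with 683 (17.8%) more than 10000 bp and 200 (5.20%) more than 100000 bp from the nearest TSS. Chromosome X held 43 regions (1.12%) and chromosome Y held 0, which by the exact interval allows up to 0.0959% of the list. The promoter share depended on its definition: it was 37.3% by the annotation class, which leaves out the exons, introns and 5' UTRs that begin at the TSS.

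**Figure D1:**
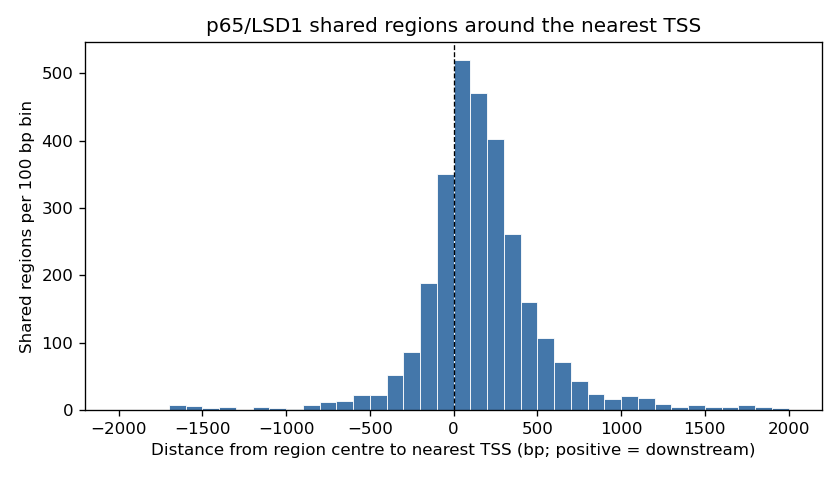
Number of shared regions (y axis) per 100 bp of distance from the region centre to the nearest TSS (x axis, in bp, positive values downstream of the TSS, dashed line at the TSS). Bars are counts of distinct regions; the highest bar, 520 regions, is the first step downstream of the TSS.

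The next comparison asked how strongly the shared regions were covered and whether those at promoters differed from the others. The regions with the highest p65 tag numbers included the promoters of Cdca4, Birc5 and Scrib, a CpG island between genes on chromosome X, and repeats. The region at Cdca4, a cell division cycle-associated gene, held 44 p65 tags (95% Poisson interval 32.0 to 59.1) and 7 LSD1 tags (2.81 to 14.4), at 114067670 to 114067905 on chromosome 12 (mm9), with its centre at −187 bp from the TSS (negative distances are upstream). The promoter of Birc5, which encodes the mitotic protein survivin, held 35 p65 tags (24.4 to 48.7) and 13 LSD1 tags (6.92 to 22.2), at 117710444 to 117710679 on chromosome 11. The promoter of the cell polarity gene Scrib held 32 p65 tags and 10 LSD1 tags, and that of Chmp4b, a membrane-remodelling ESCRT-III subunit, held 28 and 7. Fam193a held 30 p65 tags and 6 LSD1 tags, Zfp428 held 30 and 4 in a CpG island 414 bp inside the gene, and Zfp637 held 28 and 6.

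The remaining genes with the highest p65 tag numbers were nearest to regions that also held 23 to 52 LSD1 tags. A CpG island on chromosome X at 166435383 to 166435618, at −18651 bp from the TSS of G530011O06Rik, held 44 p65 tags and 52 LSD1 tags, and a second region of that gene held 32 and 35. A simple repeat in an intron, assigned to Pisd-ps3, held 35 p65 tags and 31 LSD1 tags. At the microRNA gene Mir101c on chromosome 9, 4 regions between 3015898 and 3038140 held 25 to 30 p65 tags and 23 to 31 LSD1 tags, and 3 of the 4 were in mouse major satellite repeats (GSAT_MM).

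Across the list most regions had few tags. The median was 6 p65 tags (quartiles 5 and 7, range 4 to 44) and 5 LSD1 tags (quartiles 4 and 7, range 0 to 52). Regions with 5 or 6 p65 tags made up 60.7% of the list (2332 regions, interval 59.1 to 62.2%), and 23 regions held at least 20. Within the 236 bp of the p65 region, 52 regions (1.35%) held 0 LSD1 tags and 1420 held fewer than 5.

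Promoter-proximal regions (within 1000 bp of a TSS, n = 2834) held 6.74 ± 2.55 p65 tags (mean ± SD over regions) and the 1011 distal regions 6.61 ± 2.64. Both medians were 6. A difference in medians of 0 gives p = 1 in the two-sided permutation test by construction, so that planned test carries no information here. The difference in means (0.130, two-sided permutation test, p = 0.166) did not pass. LSD1 tags were 5.50 ± 2.58 at proximal and 5.49 ± 3.41 at distal regions (difference in means 0.00989, permutation p = 0.928). Regions of the promoter annotation class held more p65 tags than the other classes pooled (mean 7.08 against 6.47, difference 0.608, permutation p = 1e-05, the smallest 100000 resamples can give), a comparison chosen after the data were seen. Both p65 medians were 6. LSD1 tags of the promoter class were also higher (mean 5.73 against 5.35, median 6 against 5), which was not tested. Across regions, which are not independent replicates, p65 and LSD1 tags were weakly related (Spearman's rho 0.102, permutation p = 0.0001, the smallest 10000 resamples can give; adjusted p = 0.000133 over 4 sets of regions; Pearson's r 0.286). Outside repeats rho was 0.0903 and r was 0.218, and in promoter-proximal regions rho was 0.0896 and r was 0.126. In the 287 regions with at least 10 p65 tags rho was 0.0970 and did not pass (permutation p = 0.100), with r at 0.489. Unlike rho, r is sensitive to the few regions with many tags of both antibodies. These include those of G530011O06Rik (44 p65 and 52 LSD1 tags) and Pisd-ps3 (35 and 31) and the satellite repeats at Mir101c. The value of r without them was not computed, so it is no evidence of a relation at p65-rich regions in general. A region with 6 tags has a Poisson interval of 2.20 to 13.1 tags, so single regions near the median cannot be ranked at this depth. This counting error and the selection of the list by p65 both limit rho. A small rho is therefore no measure of how closely p65 and LSD1 occupancy are related.

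**Figure D2:**
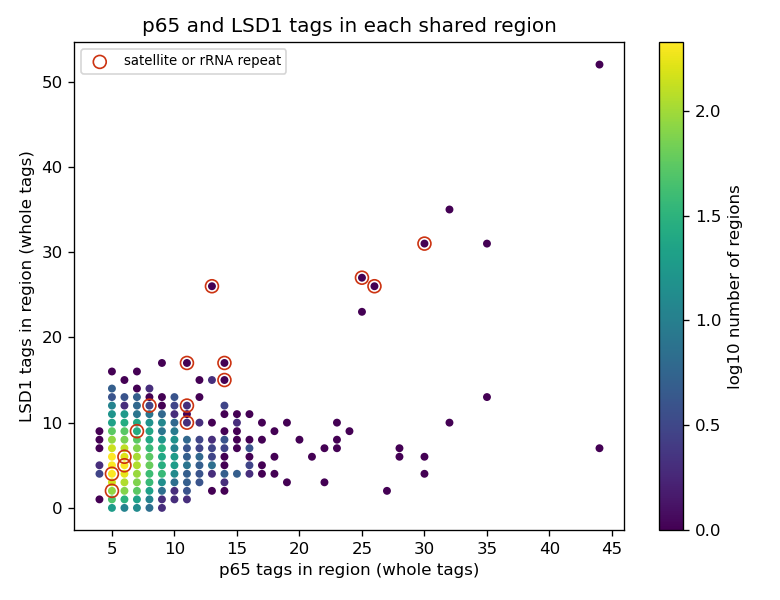
p65 tags (x axis) against LSD1 tags (y axis) in each of the 3845 shared regions, coloured by the log10 number of regions at each point; red circles mark points that hold a satellite or rRNA repeat. Most regions lie near 6 p65 and 5 LSD1 tags, and the regions with many tags of both antibodies include satellite repeats.

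Genes were then compared with lists of inflammatory, macrophage and control genes, since the title of the series concerns control of the inflammatory response by PKCα, LSD1 and NF-κB. The nearest-TSS assignment gave 3538 genes, of which 3325 were among the 21900 protein-coding genes of the reference (15.2%). Immediate early and stress feedback genes carried a shared region more often than other genes, 12 of 35 (34.3%) against 15.2% (odds ratio 2.92, 95% interval 1.32 to 6.12; two-sided Fisher's exact test, p = 0.00404, adjusted p = 0.0303 over 15 lists). The list did not pass the exact test with regions within 10000 bp of the TSS (odds ratio 1.93, adjusted p = 0.320), within 1000 bp (1.21, adjusted p = 0.835), above the median of p65 tags (2.55, adjusted p = 0.825), with at least 5 LSD1 tags (3.16, adjusted p = 0.0879) or by overlapping transcript (2.56, adjusted p = 0.0799). Phlda1 had a region 7 bp from its TSS with 6 p65 and 4 LSD1 tags. Dusp2 and Dusp16, phosphatases that switch off MAP kinases, had regions at −86 bp (5 p65 and 4 LSD1 tags) and −250 bp (8 and 3 tags). The AP-1 genes Fosl2, Jun, Junb and Jund, the early transcription factors Egr1 and Nr4a1, and Ier2, Ier5 and Socs3 made up the rest, named after their values were seen. Atf3 and Btg2 had no region in the list.

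NF-κB subunit and feedback genes carried a region in 7 of 23 cases (30.4%), which did not pass the test (odds ratio 2.45, 95% interval 0.851 to 6.29, two-sided Fisher's exact test, adjusted p = 0.236). The 7 included Nfkb1, which encodes the p105/p50 subunit, with a region 55 bp from its TSS (6 p65 and 6 LSD1 tags), and Relb (79 bp, 6 and 7 tags). The promoter of Bcl3, an atypical IκB protein, held 9 p65 tags (Poisson interval 4.12 to 17.1) and 10 LSD1 tags (4.80 to 18.4) at 20407906 to 20408141 on chromosome 7. Nfkbia, which encodes the inhibitor IκBα, had a region in intron 1 of 5, at 56592954 to 56593189 on chromosome 12 and 563 bp from the TSS, with 9 p65 tags and 11 LSD1 tags (5.49 to 19.7). Nfkb2, Nfkbiz and Rel were the others. Rela, Birc3 and Cyld had no region in the list. With all reference genes as background, non-coding genes and pseudogenes included, the odds ratio was 5.76 (Fisher's exact test, adjusted p = 0.00392), but this background raised the odds ratio of every list with a region, housekeeping genes included (from 0.931 to 2.19).

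The cytokine, chemokine, inflammatory effector and interferon-stimulated lists did not pass the adjusted test against other genes. This does not show that they carry regions as often as other genes, since short lists leave little room to detect a deficit. Each of these lists lay well below the 15.2% of all protein-coding genes. They were tested 1 by 1 and not pooled by themselves, so a deficit over all of them was not tested. Of 26 cytokine genes only Vegfa had a region (3.85%, odds ratio 0.223, Fisher's exact test, adjusted p = 0.311), with 2 regions in intron 1 that held 6 and 5 p65 tags. None of 19 chemokine genes had one (upper exact limit 17.6%, Fisher's exact test, unadjusted p = 0.100, adjusted p = 0.250). No lower count is possible, so in a list of this size the test could not have shown a deficit. Of 32 inflammatory effector and surface molecule genes only Hif1a, a hypoxia-inducible transcription factor, had any (3.13%, odds ratio 0.180, Fisher's exact test, adjusted p = 0.236). Its 2 regions lay 68 bp (5 p65 and 5 LSD1 tags) and 876 bp (7 and 4 tags) from the TSS. None of 28 interferon-stimulated genes had a region, again the lowest possible count (upper exact limit 12.3%, Fisher's exact test, unadjusted p = 0.0160, adjusted p = 0.0800). Il6, Il1b, Tnf, Ccl2, Csf1, Csf2, Ccl12, Ccl17, Cd274, Cd40, Ch25h and Cmpk2 were among the genes without a region. A region with too few tags to be listed would not be detectable at this depth.

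The list of LSD1 complex genes, which also holds Prkca for the kinase PKCα named in the title of the series, carried a region in 8 of 18 cases (44.4%, exact interval 21.5 to 69.2%), more often than other genes (odds ratio 4.48, 95% interval 1.53 to 12.6; two-sided Fisher's exact test, p = 0.00293, adjusted p = 0.0303). Without Prkca, which does not encode a component of these complexes, the count was 7 of 17 (41.2%) and the list did not pass (odds ratio 3.92, exact test, adjusted p = 0.0662). Nor did the full list pass the exact test with regions within 10000 bp (4.14, adjusted p = 0.0925), within 1000 bp (3.62, adjusted p = 0.243), above the median of p65 tags (1.91, adjusted p = 0.890), with at least 5 LSD1 tags (3.51, adjusted p = 0.203) or outside repeats (3.85, adjusted p = 0.0655). Kdm1a itself had a region in exon 1 of 19, at 136158226 to 136158461 on chromosome 4 and 295 bp from the TSS, with 6 p65 tags (2.20 to 13.1) and 5 LSD1 tags (1.62 to 11.7). Prkca had a promoter region 66 bp from its TSS, at 108205019 to 108205254 on chromosome 11, with 5 tags of each antibody. The others were Hdac1, Mta1, Mta3, Phf21a, Rcor2 and Zmym2, which encode deacetylase, NuRD and corepressor components.

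The other lists did not pass the test. LPS receptor and signalling genes carried a region in 5 of 33 cases (15.2%: Irf5, Map3k7, Tab1, Tab2 and Tbk1), macrophage lineage genes in 5 of 30 (16.7%: Cebpa, Cebpb, Cebpd, Maf and Runx1) and apoptosis and survival genes in 3 of 20 (Mcl1, Pim1 and Pim3), each with adjusted p = 1 in the exact test. Markers of other cell types were represented by 0 of 12 neutrophil genes (adjusted p = 0.390), 1 of 12 B cell genes (Ebf1, adjusted p = 1) and 0 of 16 T cell and NK cell genes (adjusted p = 0.311, each by the exact test). In the neutrophil and the T cell and NK cell lists no lower count is possible. Their unadjusted exact p values were 0.234 and 0.154, so the test could not have shown a deficit there. Liver and neuron genes had a region in 4 of 24 cases (16.7%: Map2, Neurog2, Snap25 and Syn1) and housekeeping genes in 3 of 21 (14.3%: Actb, Hprt and Rpl32), each with adjusted p = 1 in the exact test. All 4 of the liver and neuron genes with a region were neuronal, and no liver gene had one. The joint share therefore describes neither part, and the parts were not tested apart.

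**Figure D3:**
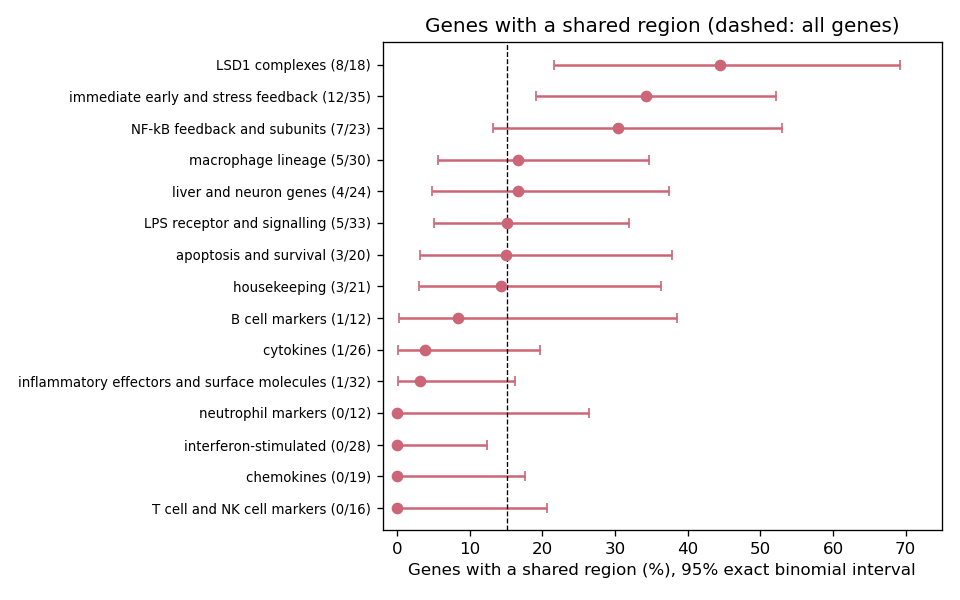
Percent of the genes in each list that had a shared region (x axis), with counts beside the list names; points are shares and bars exact 95% binomial intervals. The dashed line marks the share over all protein-coding genes, 15.2%; LSD1 complexes (44.4%) and immediate early and stress feedback genes (34.3%) lie highest, and 4 lists are at 0.

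Immediate early genes had their region close to the TSS less often than other genes. Of the 12 immediate early genes with a region, 5 (41.7%) had one within 1000 bp, against 2655 of 3313 other genes (80.1%; odds ratio 0.177, two-sided Fisher's exact test, p = 0.00384, adjusted p = 0.0422 over 11 lists). The region of Jun lay at −109166 bp from its TSS, that of Socs3 at 38413 bp and that of Nr4a1 at −12697 bp, each in a CpG island between genes. Those of Fosl2 (−1335 bp), Jund (1180 and 1940 bp) and Junb (2339 bp) lay outside 1000 bp but within 2500 bp. Both regions assigned to Ier2 were inside the calcium channel gene Cacna1a, in exons 18 and 46 of 46. None of the other 10 lists passed this test, with 6 of 7 NF-κB genes (85.7%) and 6 of 8 LSD1 complex genes having a region within 1000 bp. The cytokine, inflammatory effector and B cell lists had only 1 gene with a region each and could not have passed. For cytokines 0 of 1 gave an unadjusted exact p of 0.2. With a window of 2500 bp the immediate early list no longer passed, and 0 lists did.

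Most genes had a single region: 3270 had 1, 242 had 2 and 26 had at least 3. The genes 5730507C01Rik and 1700030C10Rik led with 8 regions each, most of them in CpG islands between genes on chromosome 12. All 8 regions of the first and 7 of the 8 of the second lay more than 100000 bp from the TSS they were assigned to. Mir101c, the DNA repair gene Mms22l and Nol4l were assigned 4 each, and those of Mms22l lay between −977294 and −212022 bp from its TSS. Genes of the 5 inflammatory lists that had a region had more of them, 1.29 ± 0.463 (mean ± SD, n = 21) against 1.09 ± 0.345 (n = 3517), a difference of 0.200 (two-sided permutation test, p = 0.0249). With regions closer than 500 bp merged the difference was 0.123 (permutation p = 0.0687), and with regions above the median of p65 tags 0.0722 (permutation p = 0.281).

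The design also pairs LPS with no treatment for LSD1 and for p65. The values used here are all from LPS-treated cells, so neither the effect of LPS on occupancy nor a background from the input libraries was measured, and the shares above describe the list after LPS alone.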

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

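The alternatives by p65 tags, LSD1 tags, repeats, repeated entries, means, overlapping transcript and a list without Prkca were chosen after the data were seen; the others were fixed before the data were examined. Of 132 alternatives, 86 kept the direction and the side of the threshold, or moved a value by less than its interval or a count by less than 1.5 times. Part of the 86 could not have come out otherwise. The chemokine, interferon-stimulated, neutrophil and T cell and NK cell lists had 0 genes with a region. Settings that only remove regions therefore left their odds ratio at 0, so the 86 is not a measure of robustness. Except where a setting itself defines the change (a wider window, fewer regions), the cause was not tested. No paired analysis was possible because the list holds no value per library; for the same reason the edgeR and DESeq2 fits, the replicate block and leaving out each replicate were not run. The κB motif search and the background matched on gene length were not run, as they need mm9 sequence or coordinates.

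The 3845 regions fell to 1504 above the median of p65 tags and to 2425 with at least 5 LSD1 tags, and the 3538 genes to 1447 and 2311. The promoter-proximal share of 73.7% was 65.5% with a 500 bp window, 77.4% with 2500 bp, 37.3% by the promoter class, 75.7% above the median of p65 tags and 80.9% outside repeats, a filter that removes intronic and intergenic regions only. The difference in p65 tags passed the test only as means of the promoter class (0.608).

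The odds ratio of immediate early genes (2.92) no longer passed Fisher's exact test within 10000 bp (1.93, adjusted p = 0.320), within 1000 bp (1.21, 0.835), above the median of p65 tags (2.55, 0.825), with at least 5 LSD1 tags (3.16, 0.0879) or by overlapping transcript (2.56, 0.0799). That of LSD1 complexes (4.48) no longer passed the exact test within 10000 bp (4.14, adjusted p = 0.0925), within 1000 bp (3.62, 0.243), above the median of p65 tags (1.91, 0.890), with at least 5 LSD1 tags (3.51, 0.203) outside repeats (3.85, 0.0655) or without Prkca (3.92, 0.0662). The NF-κB list passed the exact test with all reference genes as background (5.76, adjusted p = 0.00392), a background of added non-coding genes and pseudogenes that raised every list with a region, housekeeping genes from 0.931 to 2.19. The number of lists with fewer regions near promoters went from 1 to 0 with a 2500 bp window. The difference in regions per gene fell to 0.123 (permutation p = 0.0687) with merging and to 0.0722 (p = 0.281) above the median of p65 tags.

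Lists that never passed crossed an odds ratio of 1 in 21 alternatives. LPS signalling (0.998) was 1.16 within 10000 bp, 1.29 within 1000 bp, 2.35 with all genes and 1.08 outside repeats. Apoptosis and survival (0.986) was 1.15, 1.28, 2.32 and 1.07 in these, and 1.01 with at least 5 LSD1 tags. Housekeeping (0.931) was 1.08, 1.21, 2.19 and 1.01, and 1.52 with at least 5 LSD1 tags. Liver and neuron genes (1.12) were 0.929 within 10000 bp, 0.657 within 1000 bp and 0 above the median of p65 tags. B cell markers (0.508) were 1.19 with all genes, 1.39 above the median of p65 tags and 1.11 by overlapping transcript. Macrophage genes (1.12) were 0.650 with at least 5 LSD1 tags.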

Other observations

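The tests of gene families, the pooled gene lists, the 1000 bp limit on developmental genes, the halving of X tags and the repeat comparison were chosen after the results were seen; those of developmental genes at any distance and of X gene content were set before their results were known. Gene families, taken as all symbols that share their first letters and count at least 25 protein-coding genes, were compared in the same way as the fixed lists. Of 71 families, 5 carried shared regions more often than other genes and 7 less often (two-sided Fisher's exact test, Benjamini-Hochberg adjustment). By this exact test the 5 were symbols starting with Map, mainly MAP kinases and microtubule-associated proteins (19 of 47, 40.4%, adjusted p = 0.000592), the deubiquitinases Usp (21 of 56, 37.5%, adjusted p = 0.000651), the small GTPases Rab (21 of 69, 30.4%, adjusted p = 0.0103), the ubiquitin-conjugating and activating enzymes Ube (14 of 42, 33.3%, adjusted p = 0.0258) and the RING finger proteins Rnf (22 of 83, 26.5%, adjusted p = 0.0485). Olfactory receptors (11 of 1110, 0.991%, adjusted p = 2.79e-62), vomeronasal receptors (7 of 355, 1.97%, adjusted p = 1.88e-15), cytochromes P450 (3 of 99, 3.03%, adjusted p = 0.00271), keratins (0 of 53), Pramel genes (0 of 47), taste receptors (0 of 38) and claudins (0 of 35) were below by the exact test.

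Among the 1320 intronic and intergenic regions, the classes for which the annotation names repeats, 358 were in a repeat (27.1%, exact interval 24.7 to 29.6%). Simple repeats made up 167 and LINE elements 140 of these, and 103 of the LINE regions were in L1Md_T, a young mouse L1 subfamily. The L1Md_T regions had medians of 6 p65 and 5 LSD1 tags, the same as the regions with no annotated repeat. In 11 rRNA repeats the medians were 11 and 12 tags, and in 4 satellite repeats 25.5 and 26.5 tags.

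Shared regions sat mostly at promoters and CpG islands, and it stays open whether joint occupancy follows genes of the inflammatory response as a whole. The 5 inflammatory lists and the interferon-stimulated list pooled had a region in 21 of 163 genes (12.9%) against 15.2% of other genes, an odds ratio of 0.825 (95% interval 0.495 to 1.31), and 0.573 (0.289 to 1.03) within 1000 bp of the TSS. This pool averages over lists on both sides of 15.2%. Immediate early (34.3%) and NF-κB genes (30.4%) lay above it. Cytokine (3.85%), inflammatory effector (3.13%), chemokine (0%) and interferon-stimulated genes (0%) lay below it. Of these lists only the immediate early one passed its own test, so the pooled odds ratio describes neither side. A candidate technical explanation is that GC-rich promoters collect tags whatever the cell type uses. Developmental transcription factor and Wnt genes, which mostly have CpG-island promoters, had an odds ratio of 1.77 (1.29 to 2.40) at any distance and 1.27 (0.862 to 1.82) within 1000 bp, so the explanation is neither excluded nor borne out at the promoters themselves. Input tags at these regions, not analysed here, would separate tag-rich open promoters from p65 and LSD1 occupancy.

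Few genes on the X chromosome had a shared region, 36 of 966 (3.73%) against 3289 of 20665 autosomal genes (15.9%; odds ratio 0.205, 95% interval 0.142 to 0.286, two-sided Fisher's exact test, p = 1.56e-32). Predicted and multicopy genes on X are argued against as the whole cause, since without them the odds ratio was 0.235 (0.160 to 0.334). A single X copy is a candidate cause if the animals were male. Halving the p65 tags of autosomal regions at random left 19.6% of these regions with at least 5 p65 tags. The X share of genes was 23.4% of the autosomal share, or 27.3% without predicted and multicopy genes. LSD1 tags were not halved, and a share of regions is set against a ratio of shares of genes, so the halving cannot decide this. The labels do not give the sex, and the CpG content of X-linked promoters was not tested, so these cannot be told apart from a difference in occupancy. No biological explanation was tested.

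Satellite and rRNA regions held many tags of both antibodies, 14.6 ± 9.25 LSD1 tags (mean ± SD) and a mean of 12.8 p65 tags in 15 regions. Regions with no annotated repeat and a p65 tag number within 2 tags of theirs held a mean of 6.67 LSD1 tags, a difference of 7.93. A candidate explanation is that reads from many genomic copies pile up on the copy in the assembly in any library. High LSD1 tags are part of the pattern itself, and true occupancy by both proteins would give them too, so these cannot be told apart without input tags, not analysed here. No biological explanation was tested.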
